A study of Homo sapiens with 5 samples.

How the data were processed

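G4 structures were mapped in LNCaP cells by chromatin immunoprecipitation with the BG4 antibody and sequencing. Per the labels, chromatin was cross-linked with formaldehyde and sonicated. The 5 samples are 4 BG4 replicates and 1 input, grouped by their titles. The input has no peak list of its own. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie2 2.2.5, SAMtools 1.11 and MACS2 2.1.1 were used with the hg19 build. Their settings are not given in the sources used here. The authors deposited 1 list of narrow peaks per BG4 replicate, so peaks were called per replicate and not on pooled reads.

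Each deposited list gives, per peak, its position, a whole-number score from the authors' caller, the fold enrichment at the summit over the local background, the −log10 p and −log10 q of the summit as the authors' caller wrote them, and the distance of the summit from the start. The score was not used. The deposited fold and −log10 q served to describe, rank and filter peaks within their own list, and the fold was also tested between shared and unshared peaks of a list. Folds of the named regions are given for each list side by side, on the scale of that list. The lowest deposited −log10 q in a list lay between 1.30 and 1.37, and the lowest fold between 1.28 and 1.30.

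The reads behind each peak were recovered from the deposited values. MACS2 takes the fold as the ratio of summit reads to background, each with a pseudocount of 1, and the p from a Poisson distribution with that background. For every peak of all 4 lists, a whole number of summit reads gave back the deposited −log10 p within 0.001. With the p-values of a list shuffled among its peaks, 0.630% to 0.867% of peaks did so. The lowest background of a list is its genome-wide level, and the steps in the recovered backgrounds give the ratio of pull-down to input reads, 0.732, 0.530, 0.642 and 0.581 for replicates 1, 2, 3 and 4. From these and the smallest peak width, taken as the caller's fragment length, depth was computed in reads per kb. The input depth came out at 4.69 reads per kb in all 4 lists, so the lists share 1 input. Peaks rest on few reads, with 6 or 7 at the weakest summit of each list, and differences between single peaks of that height are within counting error.

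Peaks on chromosomes 1 to 22, X and Y entered the comparisons, and those on the mitochondrial genome and other contigs were described apart. Peaks of different lists were shared when they overlapped by at least 1 bp. Overlapping peaks of all lists were merged, and a region with peaks of at least 2 of the 4 lists was a consensus region. Chance was measured with 1000 placements of peaks of the same widths on the same chromosomes, between the first and last peak position of the chromosome over all lists. Assembly gaps were to be left out of the placements and of chromosome lengths. Since no assembly of this build was used here, they were left in, which makes random overlap somewhat rarer than it should be. A stricter set of random regions, with each peak moved by 10 to 500 kb, was added for that reason. Within a list, medians of shared and unshared peaks were compared by permutation with 100000 resamples. Regions per chromosome were compared with the share of the spanned length by an exact binomial test, with Benjamini-Hochberg adjustment and a threshold of 0.05.

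The planned results with their tests, the other settings listed for them and the rule for named regions were fixed before the data were examined. Tests and settings added later are named as such here or in the closing section. Regions named by position are the 10 consensus regions called in most lists, with ties broken by the median within-list percentile of fold, and the 5 peaks of the highest fold in each list. Of 11 planned results, 6 were not run: the promoter share, the genomic annotation, the regions away from transcription start sites, the G4 motif share, the tests of 27 gene lists and the neighbourhood of those genes. Nor was chromosome density compared with GC content and gene density. All of these need a sequence or annotation of hg19. The gene table at hand is on GRCh38, and coordinates were not converted between builds. The density test per chromosome replaced those comparisons and was chosen after the build was known.

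The alternatives were a −log10 q of at least 3 or 5, lists of equal length, overlap of at least 50% of both peaks, summits within 100 bp, at least 3 or all 4 lists, −log10 q as the measure of strength, and each replicate left out in turn. Peaks with a background at least 5 times the genome level were left out as an added alternative. Overlap and merging were tested on simulated lists with 500 planted shared sites, of which 100% were recovered. Of 200 independent simulated placements, 2% passed the 0.05 threshold. The recovery of reads returned 100% of 2705 simulated summits. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.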

Results

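BG4 is an antibody fragment that binds G-quadruplexes (G4s), 4-stranded DNA structures held together by guanines. Chromatin bound by BG4 was sequenced from LNCaP, an established androgen-sensitive prostate cancer cell line, to map endogenous G4s and to relate them to enhancers. The series holds 5 samples, 4 BG4 pull-downs and 1 input. Each BG4 replicate has its own list of peaks on the hg19 build, and the input entered the lists as the background against which peaks were called. The design therefore holds 1 group, and the comparisons are between its replicates and between parts of the genome. Nothing in the labels says whether the 4 replicates came from separate cultures, so the spread between them may be technical.

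The replicates differed widely in how much of the genome was called. Replicate 1 had 6740 peaks, replicate 2 had 1746, replicate 3 had 3805 and replicate 4 had 2281, a mean of 3643 ± 2241 (SD, n = 4) and a 3.86-fold range. The peaks covered 2.66, 0.675, 1.42 and 0.892 Mb in the same order (1.41 ± 0.891 Mb, SD, n = 4). The peaks of the 4 lists were alike in size. Their median width lay between 323 and 346 bp, and the median fold enrichment over background, as the authors' peak caller gave it, was 6.51 ± 0.10 (SD, n = 4). The highest fold in a list was 29.6 in replicate 1, 18.4 in replicate 2, 20.7 in replicate 3 and 22.01 in replicate 4. The depth recovered from the deposited values was 3.43 reads per kb for replicate 1, 2.48 for replicate 2, 3.01 for replicate 3 and 2.72 for replicate 4. The same recovery gave 4.69 reads per kb of input in all 4 lists. The median peak summit held between 14 and 16 reads, so a single peak rests on few reads.

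Most peaks of the shorter lists lay in regions that another list also called. On chromosomes 1 to 22, X and Y, 88.7% of the peaks of replicate 2 overlapped a peak of replicate 1 by at least 1 bp, as did 80.7% of those of replicate 3 and 85.1% of those of replicate 4. Replicate 3 overlapped 78.9% of the peaks of replicate 2 and 73.0% of those of replicate 4, and replicate 4 overlapped 60.5% of the peaks of replicate 2. These are shares of the shorter list of each pair. As shares of the longer list the overlaps were lower. They ran from 22.4% of the peaks of replicate 1, with replicate 2, to 46.3% of those of replicate 4, with replicate 2. Peaks of the same widths placed at random on the same chromosomes overlapped in 0.0895% to 0.264% of cases on average, and in 0.793% at most. Peaks moved by 10 to 500 kb, the stricter comparison, overlapped in 0.195% to 0.567% of cases on average and in 1.28% at most. All 6 overlaps exceeded every one of 1000 placements of either kind (one-sided permutation test, p = 0.001 for each, also after Benjamini-Hochberg adjustment over the 6 pairs, the smallest value that number of placements can give). Because 1 input served all 4 lists, part of the overlap may be shared background.

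Merging the lists gave 7520 regions. Of these, 3966 were called in a single list, 1634 in 2 lists, 1034 in 3 lists and 886 in all 4. The 3554 regions called in at least 2 lists, here the consensus regions, covered 1.72 Mb with a median width of 446 bp. Random placement gave 26.0 such regions on average and 44 at most (one-sided permutation test, p = 0.001, the smallest possible). It gave at most 1 region in at least 3 lists, against 1920 observed, and none in all 4. Moved peaks gave 63.8 consensus regions on average and 91 at most, with at most 6 regions in at least 3 lists and 1 in all 4 (one-sided permutation test, p = 0.001 for each count, the smallest possible). The count of consensus regions depended on the lists used. It was 2030 without replicate 1 and 2357 without replicate 3. It was 1717 when each list was shortened to the 1640 peaks of highest −log10 q, the length of the shortest list. Without replicate 2, the remaining 3 lists had 1475 regions in common.

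**Figure D1:**
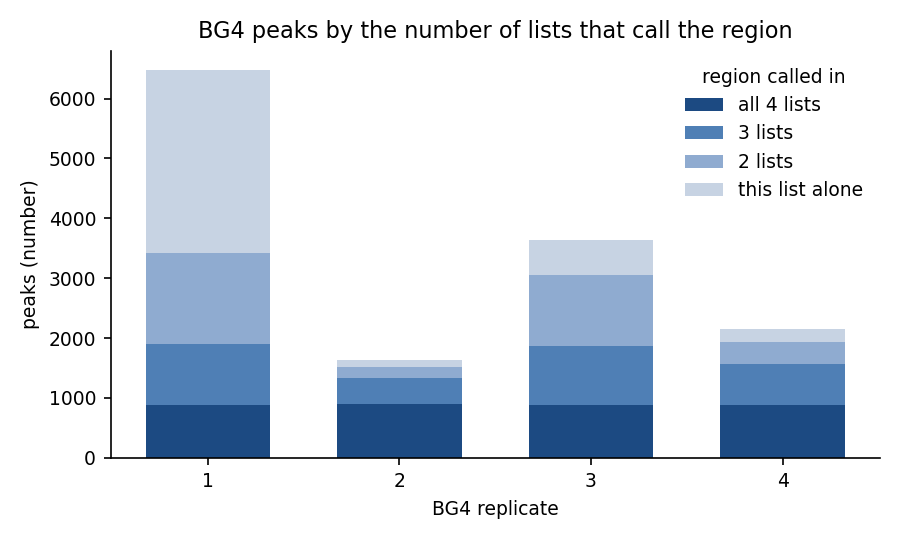
Number of peaks on chromosomes 1 to 22, X and Y (y axis) in each BG4 replicate (x axis), with the bar divided by the number of lists that call the region. Between 887 and 893 peaks of each replicate lie in regions called in all 4 lists, while 3054 peaks of replicate 1 lie in regions that no other list calls.

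The regions named here were chosen for their fold, the 10 strongest among those called in all 4 lists and the 5 highest folds of each list. Positions are in hg19. A region on chromosome 8, from 12051483 to 12052556, was the only one among the 5 highest folds of all 4 lists. Its fold was 27.8 in replicate 1, 18.4 in replicate 2, 20.7 in replicate 3 and 19.9 in replicate 4, with 62 to 108 reads at the summit over a background 2.99 to 4.27 times that of the genome. A region on chromosome 1, from 172501724 to 172502381, reached folds of 13.5 to 22.5 over the genome background itself. The region on chromosome 21 from 37528522 to 37529205 held the highest fold of replicate 1, 29.6, and ranged down to 15.5. On chromosome 16, the region from 89939856 to 89940889 held the highest fold of replicate 4, 22.01, and spanned 16.6 to 27.5. The region on chromosome 1 from 228327510 to 228328107 had folds of 17.4 to 28.4, and the region on chromosome 8 from 124428452 to 124429207 had folds of 16.1 to 21.4.

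Chromosome 3 held 3 of the 10 strongest consensus regions. The region from 125634546 to 125635560 had folds of 13.5 to 24.1, the region from 75484241 to 75485245 had folds of 11.97 to 19.7, and the region from 133291918 to 133292583 had folds of 14.5 to 28.5. The last of the 10, on chromosome 22 from 36424667 to 36425426, had folds of 11.95 to 22.7. The 5 highest folds of each list gave 20 entries at 12 distinct positions, of which 8 were also among the 10 strongest consensus regions. The remaining 4 lay outside those 10. On chromosome 12, from 133066324 to 133066830, the fold was 21.0 in replicate 1 and 16.7 in replicate 2, but 11.9 in replicate 3 and 5.58 in replicate 4, where 10 reads lay at the summit. On chromosome 19, from 10946194 to 10946866, the fold ranged from 9.76 in replicate 2 to 21.7 in replicate 4. The region on chromosome 22 from 29279086 to 29279673 had folds of 12.3 to 17.5, and the region on chromosome 20 from 33463834 to 33464471 had folds of 13.5 to 19.6. All 14 regions were called in 4 of 4 lists. With a −log10 q of at least 5, or with lists of equal length, the chromosome 12 region was called in 3. What lies at these positions, including genes, promoters and G4 motifs, was not analysed here, since the annotation at hand is on another build.

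Peaks found by more than 1 list had the higher median fold in each list. In replicate 1, the 3422 peaks shared with at least 1 other list had a median fold of 7.48, against 5.63 for the 3054 peaks of that list alone. The medians were 6.80 against 5.39 in replicate 2, 6.80 against 5.69 in replicate 3 and 6.69 against 5.55 in replicate 4. The ratio of the 2 medians was 1.248 ± 0.062 (SD, n = 4) and lay above 1 in 4 of 4 lists (two-sided permutation test within each list over 100000 resamples, p = 1e-05 each, also after Benjamini-Hochberg adjustment over the 4 lists, the smallest possible). Peaks are not independent samples of the culture, so these p-values describe the lists. A peak counts as shared only if it also passes the cut of another list. Peaks near the cut would therefore be shared less often even if all replicates had the same signal.

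The share of shared peaks was higher in the highest fold decile than in the lowest in each list, though not every step between deciles was upward in replicates 2 and 4. In replicate 1, 27.7% of the peaks in the lowest fold decile were shared (95% Wilson interval 24.4% to 31.2%), against 96.0% in the highest (94.2% to 97.2%). The shares were 82.3% and 100% in replicate 2, 71.7% and 99.7% in replicate 3 and 81.3% and 100% in replicate 4, where the next decile above the lowest had 77.6%. Over whole lists, 52.8% of the peaks of replicate 1, 92.9% of replicate 2, 84.0% of replicate 3 and 90.1% of replicate 4 were shared (80.0 ± 18.5%, SD, n = 4). These intervals cover counting error only. Across the 886 regions called in all 4 lists, the rank order of fold was similar between lists, with Spearman's rho from 0.52 for replicates 2 and 4 to 0.71 for replicates 1 and 3. These correlations are across regions, which are not independent replicates. The folds of all 4 lists also rest on the same input, which may raise the correlations. They were not computed without regions of high background.

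**Figure D2:**
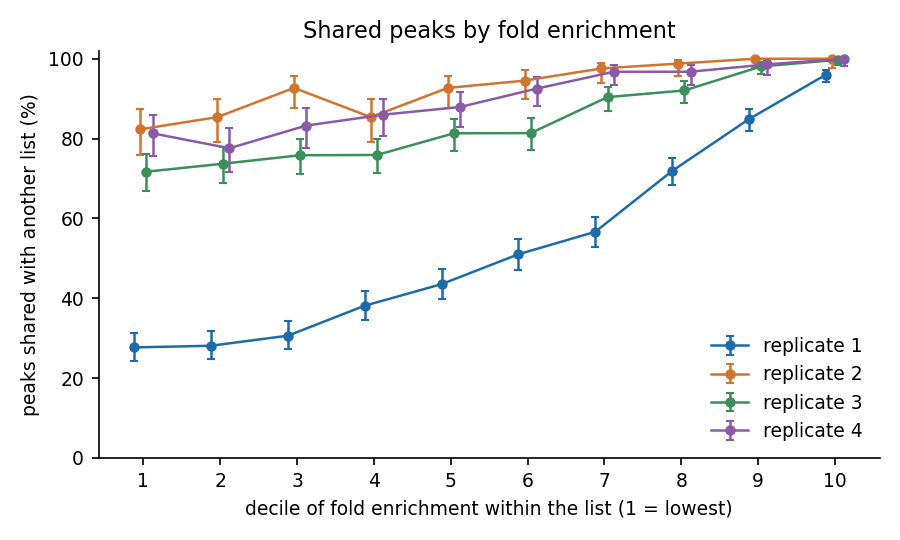
Share of peaks that another list also calls (y axis, percent) by decile of fold enrichment within the list (x axis, from lowest to highest), 1 line per BG4 replicate with 95% Wilson intervals. Replicate 1 climbs from 27.7% to 96.0%, and replicate 2 from 82.3% to 100%.

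Consensus regions were unevenly spread over the chromosomes. Chromosome 19 was the densest, with 341 regions or 5.78 per Mb, which was 4.87 times the density of all chromosomes together (1.19 per Mb). The peaks of the single lists gave 4.99 ± 0.48 times (SD, n = 4). Chromosome 22 had 2.999 times the overall density (2.90 ± 0.18 in the single lists, SD, n = 4), chromosome 17 had 2.52 times (2.58 ± 0.15, SD, n = 4) and chromosome 16 had 2.13 times (2.19 ± 0.20, SD, n = 4). At the other end, chromosome X held 42 regions, 0.231 times the overall density (0.233 ± 0.052 in the single lists, SD, n = 4). Chromosome Y held 6 regions, chromosome 6 had 0.383 times the overall density and chromosome 13 had 0.445 times.

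Of the 24 chromosomes, 9 lay above the overall density and 11 below it, and 4 did not pass (two-sided exact binomial test with Benjamini-Hochberg adjustment over the 24). For chromosome 19 the adjusted p was 1.84e-122. The other chromosomes above were 20 at 1.499 times, 14 at 1.37, 1 at 1.33, 11 at 1.33 and 12 at 1.199, the last with an adjusted p of 0.0148 in the exact test. Those below also included chromosomes 2, 3, 4, 5, 8, 18 and 21, between 0.521 and 0.776 times. Chromosomes 7, 9, 10 and 15 did not pass. All 20 differences had the same direction in 4 of 4 lists. The consensus regions were built from these lists, so this is not an independent check. The test counts neighbouring regions as independent, and lengths include assembly gaps, which lowers the values of chromosomes with long gaps such as Y. Chromosome copy number was not taken into account either. Fewer copies leave fewer reads to call, so the low values of X and Y may partly reflect copy number.

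**Figure D3:**
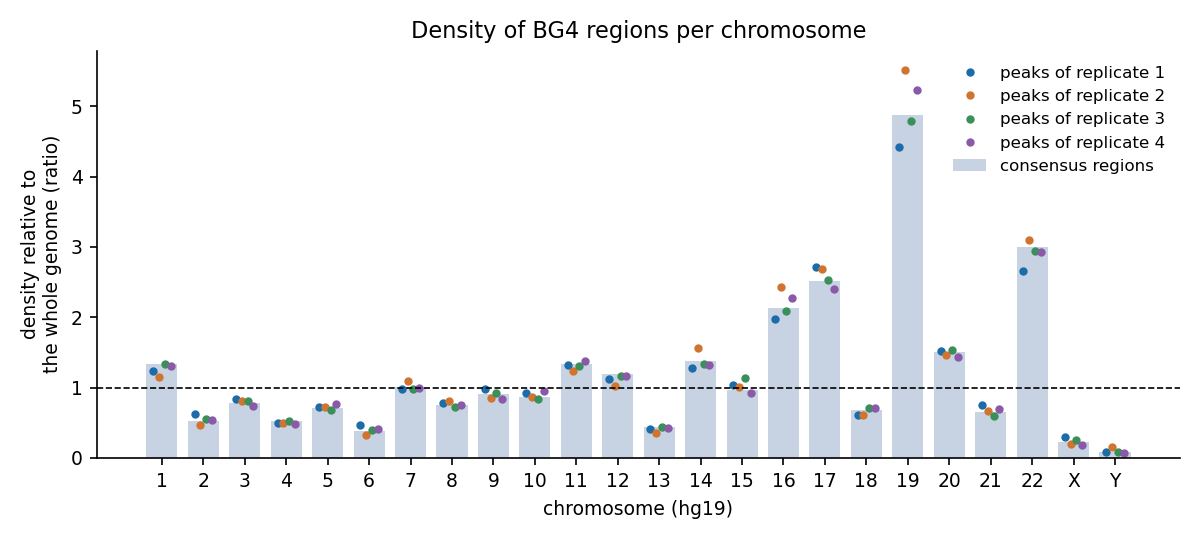
Density per Mb relative to all chromosomes together (y axis, ratio) for each chromosome (x axis), with bars for the consensus regions and a point for the peaks of each BG4 replicate; the dashed line marks a ratio of 1. Chromosome 19 stands at 4.87, with the replicates between 4.42 and 5.51, and chromosome X at 0.231.

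Some of each list lay outside these chromosomes. The mitochondrial genome was called as 1 peak over nearly its whole length in each list, with a fold of 1.41 in replicate 1, 1.97 in replicate 2, 1.62 in replicate 3 and 1.86 in replicate 4. Unplaced and alternate contigs held 263, 105, 159 and 136 peaks (5.01 ± 1.13% of a list, SD, n = 4). The contig GL000220.1, which carries copies of the 45S ribosomal RNA genes, held 16, 20, 18 and 29 of them, with a median fold of 2.15, 1.76, 1.98 and 2.38. A single peak near its start, at 6986 to 7885 in replicate 1, had the highest fold of the contig in each list, 9.38 in replicate 1 and 5.42, 6.45 and 6.08 in replicates 2, 3 and 4.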

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

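The tests of the mitochondrial genome and of GL000220.1 were chosen only after these peaks had been seen. Of 51 sets of 4 replicate values, 4 held a replicate far from the other 3. Chance marks about 1 in 20 sets of unselected values, but 14 of the 51 sets are folds of regions chosen for a high fold, for which this rate does not hold. Replicate 2 had a density of 0.154 times the overall density on chromosome Y, from 5 peaks, against 0.0832 in the next replicate. Replicate 1 had a fold of 28.4 in the chromosome 1 region from 228327510, against 18.0 in the next. Replicate 2 had a fold of 11.97 in the chromosome 3 region from 75484241, against 18.8 in the nearest. Replicate 3 had a fold of 19.6 in the chromosome 20 region from 33463834, against 14.2 in the nearest. Folds are on the scale of their own list, so these differences are given as values only.

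The mitochondrial genome, with 4 peaks, and GL000220.1, with 83 peaks over the 4 lists, lay outside the comparisons and were called in every list. Whether high copy number in the input accounts for the calls stays open, since the median background over these peaks was at least 245.93 times the genome level in every list but a call already divides by that background. A ceiling of 1 read per position and strand may act on the mitochondrial genome, where the summit reads divided by that ceiling, 2 times the smallest peak width, gave 1 in all 4 lists and the folds of 1.41 to 1.97 lay near the 1.37 to 1.89 given by the ratio of input to pull-down depth alone. On GL000220.1 the ceiling was not reached in any list. The highest summit lay at 86.1% to 98.2% of it and the input at 72.0% to 74.8%. Summits this near the ceiling may still be held down by it, so its part stays open. The median folds of the contig were 2.15, 1.76, 1.98 and 2.38 in replicates 1 to 4. The depth ratio alone gives 1.37, 1.89, 1.56 and 1.72, above the median fold in replicate 2 and below it in the others. A bound of 10 times on every single peak, first set for copy number, was not met by the GL000220.1 peak near its start in replicates 1, 2 and 3, at 8.40 to 9.39 times, and was moved to the median after this was seen, and no biological explanation was tested.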

How the results depend on the processing

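The alternatives that left out peaks of high background, kept only peaks with at least 2 times the genome background, or moved peaks by 10 to 500 kb were chosen after the data had been seen. All tests of overlap, of peak strength and of the density of chromosome 19 kept their direction and their side of the threshold under every alternative run. The mean overlap of the 6 pairs, as a share of the peaks of the shorter list, was 77.8%. It was 56.6% for lists of equal length, the lowest value, and 63.5% for summits within 100 bp. Among peaks with at least 2 times the genome background it was 71.3%, and with 1 replicate left out 70.8% to 82.8%. The ratio of median folds ranged from 1.18 to 1.27 over the alternatives that use fold, and chromosome 19 stayed between 4.82 and 5.36 times the overall density. Consensus regions numbered 3554, and 3407 without peaks of high background, 1717 with lists of equal length, 1920 in at least 3 lists and 886 in all 4. With 1 replicate left out they numbered 2030 to 3368, the lowest without replicate 1. Regions called in all lists numbered 886, and 801 without peaks of high background and 573 with lists of equal length. With 1 replicate left out, the remaining 3 lists shared 908 to 1475, the highest without replicate 2. Fewer lists or peaks by construction set these counts. The mean peak number was 2611 to 4275 and the covered length 0.997 to 1.66 Mb with 1 replicate left out. Of the 14 named regions, 13 were called in 4 lists under all 4 settings tried, and the chromosome 12 region from 133066324 in 3 under 2 of them. The alternatives of the 6 planned results named under processing were not run. No paired analysis was possible because the design has 1 group of pull-downs. Weak peaks rest on few reads, with 6 or 7 at the weakest summit of each list, so their calls may depend on depth.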

Other observations

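The tests of the spacing of regions and the count of stronger peaks after thinning were chosen only after the results had been seen. Consensus regions lay close to each other more often than random ones. Of the 3554 regions, 11.7% had a neighbour within 10 kb, against 3.85% on average for regions placed at random and 7.94% for regions moved by 10 to 500 kb, which keeps the broad distribution along the chromosomes (permutation test, p = 0.001 for both, the smallest possible). Within 1 kb the share was 3.91%, against 0.561% for regions placed at random and 1.204% for moved regions. The share within 10 kb includes these close neighbours. Whether they are separate sites or parts of 1 enriched stretch was not tested. The excess within 10 kb therefore need not reflect separate sites lying close together. Within 100 kb the share was 51.01%, against 28.9% and 45.7%. Among windows of 1 Mb set at whole Mb positions, the fullest was on chromosome 17, with 20 regions between 7117572 and 7835635, of which 6 were called in all 4 lists. Chromosome 16 followed with 19 regions between 30076806 and 30935000, 7 of them in all 4 lists, and with 18 regions between 2021780 and 2962375. Stretches across window edges were not compared.

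The 4 lists differed in length more than in depth. Replicate 2 had 0.724 times the depth of replicate 1 and 0.259 times its peaks. Sequencing depth alone was examined by thinning the recovered summit reads of the called peaks of replicate 1 to the depth of each other list. A peak was kept when its thinned summit reached the lowest −log10 p of that list. Replicates 2, 3 and 4 held 0.284, 0.578 and 0.360 times the peaks kept. When only peaks at or above the median −log10 p of the list were counted, they held 0.419, 0.678 and 0.487 times. At summits this argues against depth as the whole cause. Peaks were not called again after thinning, so a loss of peaks through their width was not modelled and the kept numbers may be too high. How far depth acts in that way stays open. Weaker enrichment in the pull-down may contribute. At the 886 regions called in all 4 lists, summit reads were divided by the genome-wide background of the list, which is its depth times the fragment length. The median of this value relative to replicate 1 was 0.828 in replicate 4 (95% bootstrap interval 0.802 to 0.848), 0.832 in replicate 2 and 0.910 in replicate 3. Other causes stay open, and no biological explanation was tested, since the design has 1 group.

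Chromosome 19 held more consensus regions per Mb than the other chromosomes. Peaks of at least 5 times the genome background are argued against as the source. Without them its density was still 4.82 times that of the genome. Few consensus regions rested on such peaks, since leaving them out took the count over all chromosomes from 3554 to 3407. Repeats of lower background were not tested. A copy number raised as far as the density is argued against as well. The median background of its peaks was 1.07, 1.125, 1.125 and 1.25 times that of peaks elsewhere in replicates 1 to 4. The 95% bootstrap interval in replicate 4 was 1.125 to 1.375, far below the excess in density. A smaller gain stays open, since these backgrounds were read only at called peaks and cannot fall below the genome level. How far such a gain would raise the number of calls was not tested. GC content, which may affect both sequencing and the number of possible G4s, and gene density were not tested and stay open.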
